A study of Mus musculus with 38 samples.

How the data were processed

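Gene expression was measured in spleen cells of DBA/2 mice, untreated or 1, 2 or 5 days after cyclophosphamide at 83 mg/kg. Per the labels' protocols, total RNA was extracted with the Qiagen RNeasy Midi kit, amplified with the Ambion Amino Allyl MessageAmp II kit, and labelled with Cy5 for the spleen samples and Cy3 for the reference. The reference is described per the labels as a pool of untreated bone marrow cells, while its treatment field names cyclophosphamide; the description as untreated was followed, and since all arrays share the reference it cancels in every comparison between groups. No dye swap was made, so the dye also cancels between groups and not in the ratios themselves. The design text speaks of 5 mice per condition, and 19 mice are present: 5 untreated, 4 at day 1, 5 at day 2 and 5 at day 5, each with 2 technical columns. Whether the 2 columns of a mouse come from 1 slide or from separate slides is not given in the sources used here. No slide, scan date or other batch is given, so none was tested.

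The deposited values are log2 ratios of spleen sample over reference; the base of the logarithm is not given in the sources used here and was taken as 2. Values are bounded at a size of 6 in either direction, a 64-fold ratio, which 7 values reach (1 upper, 6 lower), and the medians of the arrays lie between -0.0212 and 0.0132, so the authors centred them. Background correction, the filter on spots, the normalization and the software are not given in the sources used here. Of all values 63.2% are present; 3973 of 13443 probes have a value on all 38 arrays and 1083 on none. The direction of the ratio was settled in untreated mice from marker lists fixed beforehand.

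The probe table pairs 10032 probes with 1 gene, 170 with several and 3241 with none. Symbols of 10028 probes were updated through their gene identifiers in a RefSeq gene table (assembly GRCm38.p6, used for names alone) and 4 were kept as given. Probes with several genes or none were tested and not named.

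The 2 technical columns of a mouse were averaged. Probes with a value in at least 3 mice of each group were kept, 8319 (61.9%). Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes), all 4 groups sharing the spread (prior degrees of freedom 5.52, prior variance 0.0674), and p values are two-sided with Benjamini-Hochberg adjustment at 0.05. The comparisons are each day against untreated, day 2 against day 1, day 5 against day 2, and an F-test over the 4 conditions. Changes are log2 differences with the moderated standard error; folds are 2 to that power. Mice with the same number in different groups were not paired: with group means removed, 27 such pairs had a mean correlation of 0.00199.

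Gene lists, 32 in all (17 pathways and 15 cell types, 614 of 616 symbols matched), were fixed in advance and tested with cameraPR of limma on 1 probe per gene, with a preset correlation of 0.01 and adjustment over 96 tests of 32 lists on 3 days. Lists need at least 4 measured members. The same tests between days (64) were added after the data were seen. An estimated correlation was computed over probes measured on all arrays, where a list kept at least 4 members, so the members change together with the correlation. The score of a mouse is the median over a list of its values centred per probe, compared by a two-sided exact permutation test. Genes were named by a rule fixed in advance: the 10 probes that rose most and the 10 that fell most against untreated, and 5 and 5 between days, past the threshold, with every treated mouse on the same side of the untreated mean, 1 gene symbol that is no clone name, and 1 probe per gene, and up to 4 members of each list with the smallest p. List members beyond these 4 are named because they passed the test or for contrast.

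The steps were tested on simulated data with 8319 probes: of 100 probes changed 2-fold, 86 were found for day 1 against untreated, 88 for day 2 and 87 for day 5, and of 100 changed 4-fold 100, 99 and 100. Of 195, 200 and 193 calls 9, 13 and 6 were false. Each comparison held both sets of 100 changed probes, with normal noise that was independent between probes. The shares found depend on these settings and do not carry over to a comparison in which fewer probes change.

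Alternatives tried were other scalings between arrays (median centring, quantile normalization), each technical column alone or both with the mouse as a random effect, no filter or a full filter on missing values, a variance trend, array weights, averaging the probes of a gene, a block on mouse number, stricter thresholds, fits of only the groups compared, leaving out each mouse, an estimated correlation and fry for the lists. Chosen after seeing the data were a scaling to equal spread (median absolute deviation) and a fit without the 3 mice whose technical columns correlate below 0.7. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.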

Results

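Spleen cells of 19 DBA/2 mice were profiled, 5 from untreated mice and 4, 5 and 5 from mice taken 1, 2 and 5 days after cyclophosphamide at 83 mg/kg. Cyclophosphamide is an alkylating drug that damages DNA and is most toxic to dividing cells. Each mouse had 2 technical array measurements, 38 in all, each giving the log2 ratio of the spleen sample to a common pool of bone marrow cells. Of 13443 probes, 8319 had a value in at least 3 mice of every group and were tested, and 6111 of these name a single gene, for 5925 genes. A measurement held 5829 to 10407 values. The correlation between the 2 measurements of a mouse ran from 0.581 to 0.962, and was lowest in untreated mouse 4 (0.581), untreated mouse 2 (0.651) and day 5 mouse 5 (0.673). The spread of the log2 ratios within a mouse was widest on day 2 (SD 0.506 to 0.699), against 0.508 to 0.586 on day 1, 0.382 to 0.524 on day 5 and 0.41 to 0.53 without treatment. The number of mice limits the precision: the median standard error of a difference between groups was 0.174 to 0.183 on the log2 scale.

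In untreated spleens lymphocyte genes lay above the marrow pool and granule genes below it. T cell genes had a mean log2 ratio of 0.306 ± 0.185 (SD, n = 5), and mature B cell genes 0.18 ± 0.166, above 0 in 5 of 5 mice each. Genes of early granules (-0.826 ± 0.299) and of neutrophils (-1.25 ± 0.58) were below 0 in 5 of 5 mice. The values were therefore read as spleen over marrow.

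The first comparison asks what changed in the spleen 1 day after the drug. In the lists of mitosis, DNA replication and red cell precursor genes 5 of 14, 3 of 12 and 6 of 14 members fell. Each list passed with a preset correlation, and with an estimated one they had adjusted p = 0.0467, adjusted p = 0.0599 and adjusted p = 0.179 in the camera test. Cdk1, the kinase that drives entry into mitosis, fell 3.08-fold (log2 -1.62 ± 0.18 SE, 4 against 5 mice, adjusted p = 2.57e-05). Cdc20, which activates the complex that ends mitosis, fell 3.13-fold (log2 -1.64 ± 0.18, adjusted p = 2.57e-05), and the dUTPase gene Dut fell 3.09-fold (log2 -1.63 ± 0.15, adjusted p = 4.35e-06). Cdkn1a, the p53-induced inhibitor of cell cycle kinases, rose 2.15-fold (log2 1.11 ± 0.24, adjusted p = 0.0159). In all, 194 of 8319 probes changed, 78 upward and 116 downward, and 1099 had an unadjusted p below 0.05.

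**Figure D1:**
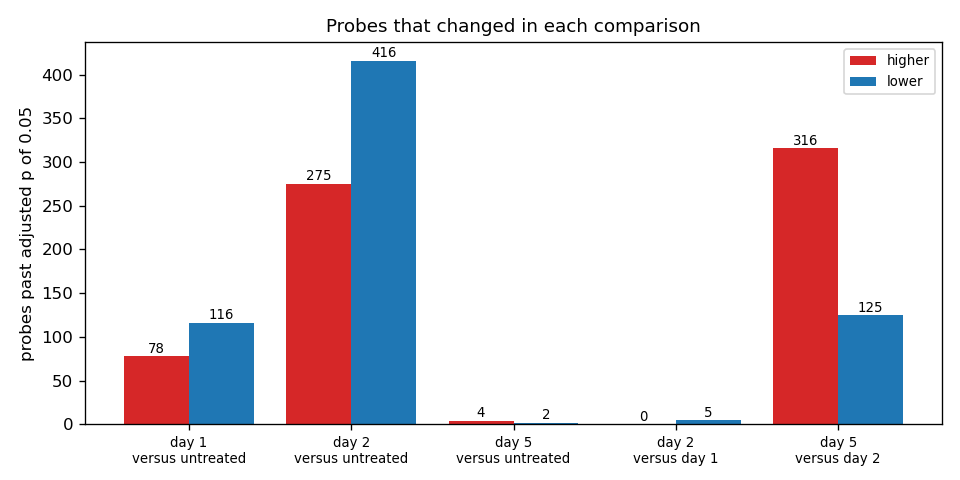
Number of probes past an adjusted p of 0.05 in each comparison, drawn as bars for probes higher (red) and lower (blue) in the first-named group, out of 8319 tested. Day 2 against untreated has the most, 275 higher and 416 lower, and day 5 against untreated has 4 and 2.

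Of 14 measured mitosis genes, 5 fell on day 1 over all genes and 6 adjusted over the list alone, and none rose. The list had a median of -0.72 and an adjusted p of 2.79e-13 in the camera test, and an adjusted p of 0.0467 with an estimated correlation. Besides Cdc20 and Cdk1, the members that fell were the spindle genes Prc1 (-1.36 ± 0.20), Nusap1 (-1.68 ± 0.28) and Tpx2 (-1.41 ± 0.31). The DNA replication list had 3 of 12 members that fell, and 7 adjusted over the list alone, at a median of -0.84 (adjusted p = 2.05e-09, and adjusted p = 0.0599 with an estimated correlation). Without untreated mouse 2 the members that fell were 5. Tyms, which makes thymidylate, fell by 1.49 ± 0.21 on the log2 scale (adjusted p = 0.000476), and the ribonucleotide reductase subunit Rrm2 fell by 1.59 ± 0.33. Sgo1, which protects cohesion at centromeres and is in neither list, fell by 1.82 ± 0.23 (adjusted p = 8.38e-05).

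Red cell precursor genes had a median of -1.08 on day 1, and 6 of 14 fell, or 7 adjusted over the list alone (adjusted p = 2.33e-08, and adjusted p = 0.179 with an estimated correlation). The members that fell were 3 without day 1 mouse 2 and 2 without the 3 mice of lowest technical correlation, where the list kept adjusted p = 6.22e-09. Rhd, which encodes the Rh blood group protein, fell 6.1-fold (log2 -2.61 ± 0.42, adjusted p = 0.00137), although its other probe gave -0.34 ± 0.37 (adjusted p = 0.79). Kel, the Kell blood group gene, fell by 1.70 ± 0.32 and Alas2, the first enzyme of heme synthesis in red cell precursors, by 1.59 ± 0.33. The largest fall among named genes was that of Mgst3, a microsomal glutathione transferase, at 6.51-fold (log2 -2.70 ± 0.32, adjusted p = 4.42e-05). The butyrophilin-like gene Btnl10 (-1.83 ± 0.39) and the cathepsin Ctse (-1.67 ± 0.34) fell as well. In the score of each mouse, the median over the list, all 4 day 1 mice lay below all 5 untreated mice for mitosis (-0.37 ± 0.25 SD against 0.45 ± 0.19), replication (-0.40 ± 0.22 against 0.48 ± 0.10) and red cell precursors (-0.32 ± 0.30 against 0.57 ± 0.09). The exact permutation p was 0.00794 for each, the smallest these numbers of mice allow here, and 0.0847 after adjustment over 96 tests.

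**Figure D2:**
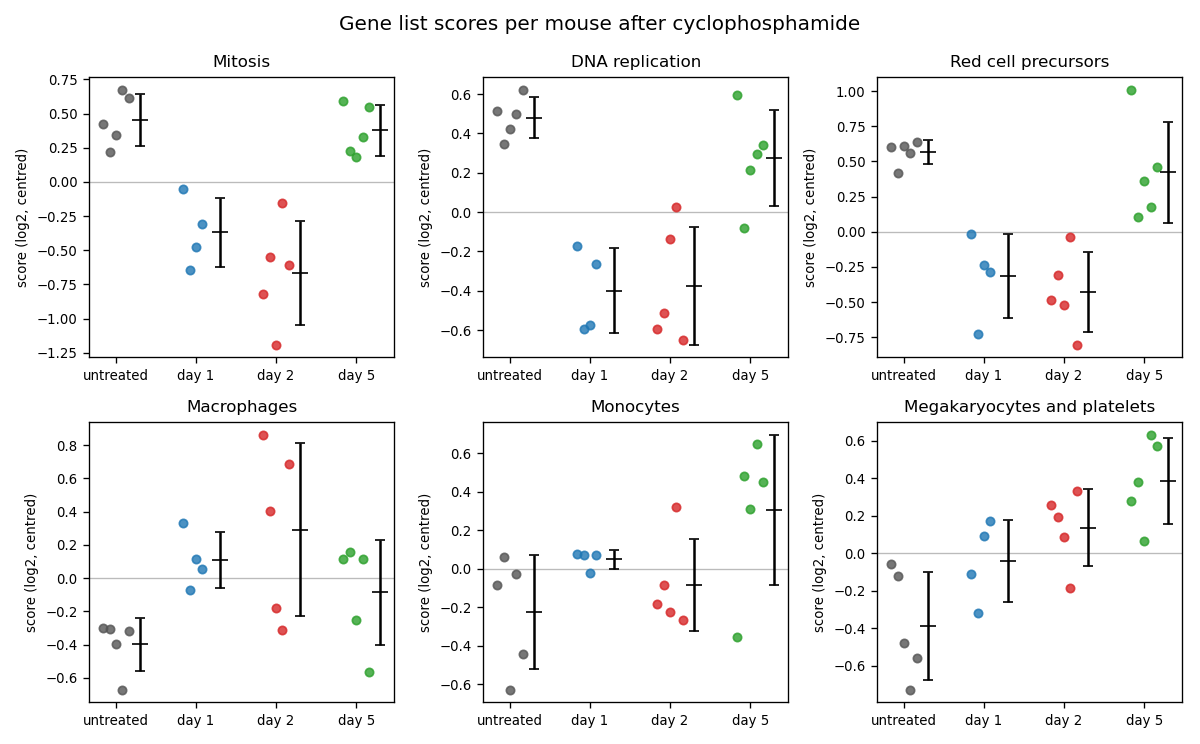
Score of each mouse for 6 gene lists, as the median over the list of log2 ratios centred on each probe's mean over mice, in 5 untreated mice and 4, 5 and 5 mice at days 1, 2 and 5. Points are mice, and the bar at their right is the mean with its SD; mitosis, DNA replication and red cell precursor scores of all day 1 and day 2 mice lie below those of all untreated mice.

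Genes of macrophages, which clear dying cells in the spleen, had a median of 0.76 on day 1. Of 8 measured, 1 rose, and 2 adjusted over the list alone (adjusted p = 0.0111, and adjusted p = 0.254 with an estimated correlation). Siglec1, a sialic acid receptor of splenic macrophages, rose by 0.77 ± 0.16 (adjusted p = 0.0124), and Adgre1, a surface antigen of mouse macrophages, had 0.97 ± 0.29 (adjusted p = 0.0844). Siglec1 missed the threshold after quantile normalization and with arrays brought to equal spread. The interferon-stimulated list had a median of 0.38 with 0 of 13 members past the threshold over all genes or adjusted over the list alone (adjusted p = 0.0416, and adjusted p = 0.521 with an estimated correlation). Its members with the smallest p were Mx2 at 0.40 ± 0.14 and the chemokine Cxcl10 at 0.93 ± 0.34. Among regulators of helper T cells (median 0.28, 1 of 7 rose by either adjustment), only the aryl hydrocarbon receptor gene Ahr rose, by 1.15 ± 0.20 (list adjusted p = 0.0494, and adjusted p = 0.407 with an estimated correlation). The inflammatory cytokine gene Il1b rose by 1.17 ± 0.18 (adjusted p = 0.00106).

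The named genes with the largest rises on day 1 were led by Selenop, a plasma carrier of selenium, at 3.33-fold (log2 1.74 ± 0.30, adjusted p = 0.00279). They also held Acp5, the tartrate-resistant acid phosphatase (1.40 ± 0.25), the collagen gene Col14a1 (1.46 ± 0.30), Dgat2, which makes triglycerides (1.27 ± 0.25), Rcn3 (1.53 ± 0.38), the extracellular chaperone Clu (2.82-fold, 1.61 to 4.96 as 95% interval), Hpcal1 (1.37 ± 0.32), the lysosomal protease Ctsc (1.32 ± 0.33), the heat shock gene Hspa1a (1.27 ± 0.31) and the sodium pump subunit Atp1b1 (1.22 ± 0.29). The calls of Rcn3, Clu, Hpcal1, Ctsc, Hspa1a and Atp1b1 were each lost in 3 to 13 of the 19 fits that leave out 1 mouse. Without the 3 mice of lowest technical correlation Acp5, Rcn3, Clu, Ctsc, Hspa1a, Atp1b1, Cdkn1a, Polk, Rrm2, Alas2, Kel and Ctse missed the threshold. With arrays brought to equal spread Rcn3, Clu, Col14a1, Ctsc, Hspa1a, Alas2 and Kel missed it, and after quantile normalization Rcn3, Clu, Col14a1, Acp5 and Ctsc. A lost call was not always a smaller change. Over all alternatives Kel stayed between -1.9 and -1.559 and Atp1b1 between 1.123 and 1.406, while the lowest values were 0.887 for Ctsc, 0.998 for Clu and 1.01 for Acp5. Among p53 targets, Cdkn1a and the repair polymerase gene Polk (0.73 ± 0.15) rose, 2 of 13, while adjusted over the list alone 3 rose and 1 fell, and the median was 0.03 (adjusted p = 0.298). Markers of stroma and endothelium had a median of 0.23 (adjusted p = 0.17), with Dcn at 1.25 ± 0.41 and Cxcl12 at 1.42 ± 0.47, which passed adjusted over the list alone (2 of 11) and not over all genes. The count of probes changed on day 1 versus untreated was 99 without day 1 mouse 2 and 109 without day 1 mouse 4, and was 116 with arrays brought to equal spread and 113 with the 3 mice of lowest technical correlation left out. The macrophage list had adjusted p = 0.052 without day 1 mouse 1 (0.00211 to 0.052 over single mice left out, past the threshold in 18 of 19), the interferon list 0.111 without untreated mouse 4 (0.0189 to 0.111, 13 of 19) and the helper T list 0.158 without untreated mouse 4 (0.0186 to 0.158, 9 of 19). After quantile normalization they had adjusted p = 0.0618, 0.33 and 0.0832, and with equal spread 0.0572, 0.19 and 0.125. Without the 3 mice of lowest technical correlation the interferon list had adjusted p = 0.0679 and the helper T list 0.183. With a block on mouse number these lists had 0.0545 and 0.102.

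On day 2 more probes changed than on day 1, and 9 of 14 red cell precursor and 6 of 14 mitosis genes fell. Both lists passed with a preset correlation, and with an estimated one they had adjusted p = 0.179 and adjusted p = 0.0467 in the camera test. Alas2 fell 15.4-fold (log2 -3.94 ± 0.32 SE, 5 against 5 mice, adjusted p = 1.24e-07) and Rhd 11.1-fold (log2 -3.47 ± 0.39, adjusted p = 6.36e-06). The other probe of Rhd fell less, at -1.33 ± 0.37 (adjusted p = 0.0311 in limma). Cdc20 fell by 1.99 ± 0.17 on the log2 scale and Cdk1 by 1.90 ± 0.17. Il1b rose 3.05-fold (log2 1.61 ± 0.17, adjusted p = 2.8e-06). In all 691 probes changed, 275 upward and 416 downward, and 1739 had an unadjusted p below 0.05.

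Red cell precursor genes had a median of -1.04 and 9 of 14 fell, by either adjustment (adjusted p = 9.46e-11, and adjusted p = 0.179 with an estimated correlation). Without the 3 mice of lowest technical correlation 4 fell, and the list had adjusted p = 1.12e-11. Kel fell by 2.41 ± 0.30, the carbonic anhydrase gene Car2 by 1.88 ± 0.50 and the transferrin receptor gene Tfrc by 0.86 ± 0.26, while the globin gene Hba-a1 had -0.13 ± 0.18 (adjusted p = 0.717) and Gata1, a master regulator of red cell formation, had -0.50 ± 0.26 (adjusted p = 0.284). Icam4, a red cell adhesion molecule outside the list, fell by 2.21 ± 0.37. The heme synthesis and iron list, which shares Alas2, Fech and Tfrc with the red cell list, had a median of -0.54, with 4 of 9 members that fell and 1 that rose, or 5 and 1 adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.521 with an estimated correlation). In it, Fech, which inserts the iron into heme, fell by 1.51 ± 0.35 and Ppox, an earlier enzyme of the path, by 1.29 ± 0.31, and the iron exporter gene Slc40a1 rose by 1.25 ± 0.26 (adjusted p = 0.00446). Slc40a1 and Ppox missed the threshold under quantile normalization and equal spread. Without day 2 mouse 2 the list had adjusted p = 0.0967, the highest of 19 such fits (lowest 0.00246, past the threshold in 17). Without the 3 mice of lowest technical correlation 2 members fell (adjusted p = 0.0314).

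Other large falls on day 2 were those of Mgst3 (11.8-fold, log2 -3.57 ± 0.30), the guanine nucleotide exchange factor gene Vav2 (11.8-fold, log2 -3.56 ± 0.27), Ube2l6, which conjugates ISG15 (-2.31 ± 0.30), the synaptotagmin Syt9 (-2.26 ± 0.43), the kallikrein gene Klk1b5 (-2.23 ± 0.34) and the tubulin gene Tuba3a (-2.22 ± 0.26). Of the mitosis genes 6 of 14 fell, or 7 adjusted over the list alone, at a median of -0.59 (adjusted p = 2.15e-11, and adjusted p = 0.0467 with an estimated correlation). Of the replication genes 7 of 12 fell, or 9 adjusted over the list alone, at a median of -0.93 (adjusted p = 2.39e-06, and adjusted p = 0.179 with an estimated correlation). Of them 4 fell without untreated mouse 5, without day 2 mouse 1 or without day 2 mouse 2. Members that fell included Tyms (-1.51 ± 0.20), the origin licensing genes Cdc6 (-1.38 ± 0.30) and Mcm6 (-1.12 ± 0.26), and the sliding clamp gene Pcna (-0.96 ± 0.24), which missed the threshold with equal spread. In the per-mouse scores all 5 day 2 mice lay below all 5 untreated mice for mitosis (-0.67 ± 0.38 SD), replication (-0.37 ± 0.30) and red cell precursors (-0.43 ± 0.28), each with an exact permutation p of 0.00794 (0.0847 adjusted).

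**Figure D3:**
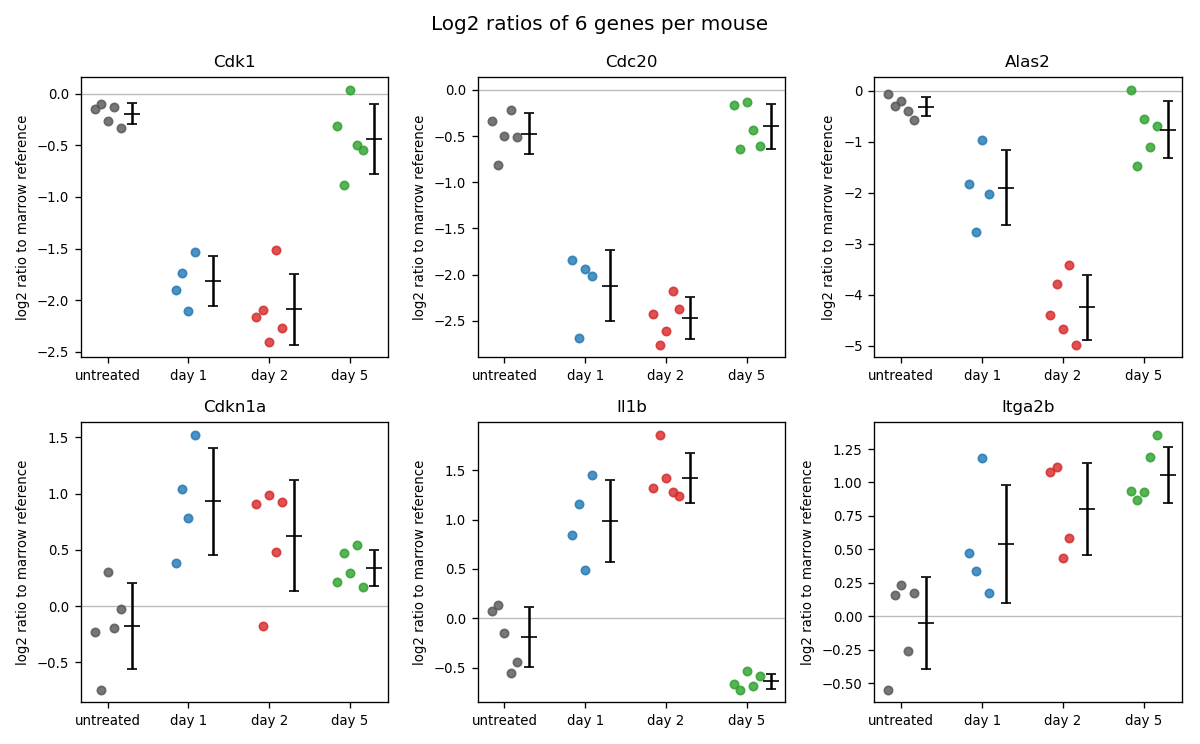
Log2 ratio of spleen to marrow pool for 6 genes in each mouse, for untreated mice and days 1, 2 and 5. Points are mice, and the bar at their right is the mean with its SD (n = 5, 4, 5 and 5, and 4 on day 2 for Itga2b); Cdk1, Cdc20 and Alas2 have their lowest means on day 2, and Itga2b its highest on day 5.

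Among genes that rose on day 2, Il1b had a further probe at 0.26 ± 0.14 (adjusted p = 0.317). Id2, a repressor of helix-loop-helix transcription factors, rose 3.02-fold (log2 1.59 ± 0.27, adjusted p = 0.000508), Slfn4, a schlafen gene of myeloid cells, 2.79-fold (log2 1.48 ± 0.34, adjusted p = 0.00759), and the amyloid precursor gene App 2.51-fold (log2 1.33 ± 0.12, adjusted p = 3.25e-07). Ccr3, the eotaxin receptor of eosinophils and basophils, rose 2.59-fold (log2 1.37 ± 0.30, adjusted p = 0.0056). The rule also took Col14a1 (1.49 ± 0.28), the complement inhibitor gene Serping1 (1.41 ± 0.32), Maged1 (1.36 ± 0.30), Kank3 (1.34 ± 0.30) and the monocarboxylate transporter gene Slc16a9 (1.45 ± 0.42, with 0.14 ± 0.16 at its other probe). Ccr3, Col14a1, Serping1, Maged1, Kank3 and Slc16a9 missed the threshold after quantile normalization and with arrays brought to equal spread.

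Macrophage genes had a median of 0.60 on day 2 and 2 of 8 rose by either adjustment, Siglec1 by 1.24 ± 0.15 (adjusted p = 2.22e-05) and the mannose receptor gene Mrc1 by 1.08 ± 0.31 (list adjusted p = 0.0383, and adjusted p = 0.299 with an estimated correlation). In the helper T list (median 0.25), 2 of 7 rose by either adjustment, Ahr by 1.19 ± 0.19 and Stat3 by 0.81 ± 0.22 (adjusted p = 0.0383, and adjusted p = 0.332 with an estimated correlation). Megakaryocyte and platelet genes had a median of 0.57 (adjusted p = 0.0494), and 1 of 6 rose, Itga2b, the platelet integrin subunit, by 0.85 ± 0.21 (3 adjusted over the list alone). Its correlation could not be estimated, since 3 members had values on every array. Izumo1r, a member of the regulatory T cell list, fell by 1.66 ± 0.17 (adjusted p = 2.18e-06), the largest change in that list, whose median was -0.12 (adjusted p = 0.131). The monocyte list had a median of 0.25 and a mean of 0.00 (adjusted p = 0.897), and in it F13a1, the coagulation factor XIII subunit, fell by 0.85 ± 0.22 (adjusted p = 0.0209) and had 0.126 with arrays brought to equal spread (adjusted p = 0.896). Of 13 p53 targets 3 rose, Cdkn1a by 0.80 ± 0.23, Zmat3 by 0.62 ± 0.17 and Polk by 0.50 ± 0.14, and the death receptor gene Tnfrsf10b fell by 0.86 ± 0.17, by either adjustment (median 0.13, adjusted p = 0.666). In the list of detoxification genes Prdx1 (0.70 ± 0.14) and Txnrd1 (0.56 ± 0.14), which reduce peroxides and thioredoxin, rose, 2 of 11 by either adjustment. Mrc1, Stat3, Itga2b, Cdkn1a, Zmat3, Polk and Prdx1 missed the threshold on day 2 under quantile normalization and equal spread, as did F13a1. Slc16a9, Maged1, Zmat3, Polk, Cdkn1a, Stat3, Mrc1, Itga2b, F13a1 and Fech missed it without the 3 mice of lowest technical correlation. The count of changed probes was 338 after quantile normalization, 345 with arrays brought to equal spread, 449 in a fit of these groups alone and 409 without the 3 mice of lowest technical correlation. Under these scalings the macrophage list had adjusted p = 0.196 and 0.258, the helper T list 0.0638 and 0.0919 and the megakaryocyte list 0.172 and 0.141. With single mice left out they passed in 13, 16 and 11 of 19 fits, with 0.102 without day 2 mouse 5 (0.01 to 0.102), and 0.116 (0.0274 to 0.116) and 0.125 (0.023 to 0.125) without untreated mouse 4. Without the 3 mice of lowest technical correlation the helper T list had adjusted p = 0.109 and the megakaryocyte list 0.073, with 0 members that rose. With a block on mouse number the macrophage list had 0.0512 and the other two 0.0655 each.

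By day 5 few probes differed from untreated spleen, and those that rose included Itga2b and the coagulation factor gene F13a1. Itga2b rose 2.15-fold (log2 1.11 ± 0.20 SE, 5 against 5 mice, adjusted p = 0.0396) and F13a1 rose 2.38-fold (log2 1.25 ± 0.22, adjusted p = 0.0396). App rose 1.63-fold (log2 0.71 ± 0.12, adjusted p = 0.0352), and 0.36 ± 0.21 at its other probe (adjusted p = 0.923), and the thrombomodulin gene Thbd, an anticoagulant receptor, rose 1.58-fold (log2 0.66 ± 0.12, adjusted p = 0.0424). In all 6 probes changed, 4 upward and 2 downward, and 434 had an unadjusted p below 0.05. The fallers were the unnamed probes 012P16 (-1.44 ± 0.23) and 014L03 (-1.57 ± 0.29), given here after their values were seen.

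The megakaryocyte and platelet list had a median of 0.86 on day 5 (adjusted p = 9.72e-09), with 1 of 6 members that rose, and 4 adjusted over the list alone. Beside Itga2b these were the platelet chemokine genes Ppbp (1.15 ± 0.28, adjusted over the list alone 0.00146) and Pf4 (1.19 ± 0.42, 0.0157) and the platelet receptor gene Treml1 (0.61 ± 0.20, 0.0115). All 5 day 5 mice scored above all untreated mice (0.39 ± 0.23 SD against -0.39 ± 0.29, exact permutation p = 0.00794, 0.0847 adjusted). The monocyte list had a median of 0.44 (adjusted p = 0.00113), with F13a1 as the 1 of 5 that rose and 3 adjusted over the list alone, the others being Clec4e (0.44 ± 0.18) and Ms4a6c (0.42 ± 0.18). In 4 of 5 mice its score was above all untreated mice (exact permutation p = 0.0476, 0.199 adjusted). The monocyte list had a median of 0.43 and an adjusted p of 0.17 after quantile normalization. Too few members of both lists had values on every array for an estimated correlation.

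Macrophage genes had a median of 0.30 on day 5 with 0 of 8 past the threshold in limma over all genes and 1 adjusted over the list alone, the complement gene C1qa at 1.84 ± 0.48 (list adjusted p = 0.037, and adjusted p = 0.521 with an estimated correlation). Regulatory T cell genes had a median of -0.26 with 0 of 6 members past the threshold by either adjustment (adjusted p = 0.0111, and adjusted p = 0.299 with an estimated correlation). Germinal centre and plasma cell genes had -0.22 with 0 of 7, and 1 that fell adjusted over the list alone, Mzb1 of antibody-secreting cells at -1.28 ± 0.31 (adjusted p = 0.0111, and adjusted p = 0.114 with an estimated correlation). The mitosis list had a median of -0.06 (adjusted p = 0.688), replication -0.19 (0.131), red cell precursors -0.11 (0.54), interferon-stimulated genes -0.10 (0.127), heme and iron -0.10 (0.688) and helper T regulators 0.25 (0.0917). The 6 calls are fragile: 0 probes passed with either technical measurement alone, with a variance trend or with probes of a gene averaged, 0 without untreated mouse 2, untreated mouse 5, day 1 mouse 4, day 5 mouse 4 or day 5 mouse 5, 1 to 3 without each of 8 other mice, and 1 without the 3 mice of lowest technical correlation. F13a1 also missed the threshold under quantile normalization and equal spread. The macrophage list had adjusted p = 0.125 without untreated mouse 4 (0.00414 to 0.125 over single mice left out, past the threshold in 13 of 19) and 0.0612 with equal spread, regulatory T 0.0687 without untreated mouse 2 (0.00607 to 0.0687) and germinal centre 0.0883 without untreated mouse 5 (0.000979 to 0.0883). Without the 3 mice of lowest technical correlation the regulatory T list had adjusted p = 0.299. With a block on mouse number the macrophage list had adjusted p = 0.0938.

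Between days 1 and 2 few probes changed, and the named ones were Alas2 and Vav2. Alas2 fell 5.11-fold (log2 -2.35 ± 0.33 SE, 5 against 4 mice, adjusted p = 0.00291) and Vav2 4.49-fold (log2 -2.17 ± 0.28, adjusted p = 0.00171). In all 5 probes changed, each downward, with 501 at an unadjusted p below 0.05. The other 3 are unnamed probes, from -2.06 ± 0.31 to -0.91 ± 0.15. The red cell precursor list had a median of -0.24, with 1 of 14 members that fell by either adjustment (adjusted p = 0.0126, and adjusted p = 0.738 with an estimated correlation), in a test added after the data were seen. The score per mouse differed by -0.11 (exact permutation p = 0.556, 0.809 adjusted). The mitosis list had -0.17 (adjusted p = 0.567). After quantile normalization, or with equal spread, 0 probes passed in limma, and the count was 9 without day 1 mouse 2 and 3 without day 1 mouse 3.

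From day 2 to day 5 Alas2, Rhd and Cdc20 rose and Il1b fell. Alas2 rose 11.3-fold (log2 3.49 ± 0.32 SE, 5 against 5 mice, adjusted p = 8.78e-07), Rhd 9.65-fold (log2 3.27 ± 0.39, adjusted p = 2.33e-05) and Cdc20 by 2.07 ± 0.17 (adjusted p = 4.52e-07). The other probe of Rhd rose less, by 1.29 ± 0.35 (adjusted p = 0.0375 in limma). Il1b fell 4.16-fold (log2 -2.06 ± 0.17, adjusted p = 4.63e-07), with -0.12 ± 0.14 at its further probe. F13a1 rose 4.29-fold (log2 2.10 ± 0.22, adjusted p = 5.41e-06). In all 441 probes changed, 316 upward and 125 downward, and 1526 had an unadjusted p below 0.05.

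Of 14 mitosis genes 6 rose from day 2 to day 5, and 7 adjusted over the list alone (median 0.62, adjusted p = 1.09e-12, and adjusted p = 0.038 with an estimated correlation), in list tests added after the data were seen. Replication genes had a median of 0.67 and 4 of 12 rose, among them Tyms (1.30 ± 0.20) and Pcna (1.13 ± 0.24), or 7 adjusted over the list alone (adjusted p = 0.000119, and adjusted p = 0.38 with an estimated correlation). Red cell precursor genes had a median of 0.92 and 8 of 14 rose, or 10 adjusted over the list alone (adjusted p = 2.5e-11, and adjusted p = 0.365 with an estimated correlation). Of the heme and iron list 2 of 9 rose, Alas2 and Fech (1.26 ± 0.35), and adjusted over the list alone 4 rose and 1 fell (median 0.44, adjusted p = 0.0211, and adjusted p = 0.727 with an estimated correlation). The repair gene Brca1 rose by 1.09 ± 0.20 and Izumo1r by 1.39 ± 0.17, and Mgst3 (2.98 ± 0.30), Vav2 (2.84 ± 0.27) and Klk1b5 (2.24 ± 0.34) also rose.

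Interferon-stimulated genes had a median of -0.34 from day 2 to day 5, and 3 of 13 fell by either adjustment, Mx2 (-0.69 ± 0.13), Rtp4 (-0.65 ± 0.15) and Ifi27l2a (-1.42 ± 0.37) (adjusted p = 0.0137, and adjusted p = 0.492 with an estimated correlation). The class I antigen presentation list had a median of -0.50 with 1 of 8 that fell, H2-T23 (-0.66 ± 0.16), and 3 adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.632 with an estimated correlation). Mature B cell genes had -0.34, and 2 of 10 fell, Cd22 (-0.96 ± 0.16) and Ms4a1, which encodes CD20 (-0.66 ± 0.18), or 4 adjusted over the list alone (adjusted p = 0.0137, and adjusted p = 0.392 with an estimated correlation). In the macrophage list (median -0.37, adjusted p = 0.567) Siglec1 fell by 0.99 ± 0.15 and C1qa rose by 1.76 ± 0.44. Plpp3, a lipid phosphatase gene, fell by 1.81 ± 0.33, Gdpd1 by 1.89 ± 0.40 and Kank3 by 1.43 ± 0.30. The neutrophil genes Cd177 (1.62 ± 0.29) and Ltf (1.48 ± 0.42), which encodes lactoferrin, rose, 2 of 9 by either adjustment, at a list median of 0.32 (adjusted p = 0.268). The count was 83 after quantile normalization and 142 with arrays brought to equal spread, where the share of risers was 86.6% against 71.7%. Gdpd1, Kank3 and Ifi27l2a missed the threshold under both of these scalings, Klk1b5 under quantile normalization and Ifi27l2a also without the 3 mice of lowest technical correlation. Pancreas genes, a sign of neighbouring tissue in the harvest, had a median of 1.28 from day 2 to day 5, with 0 of 5 past the threshold and 1 that rose adjusted over the list alone (adjusted p = 0.244).

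Most day 1 changes were shared with day 2. Of the 194 probes changed on day 1, 174 (89.7%) changed the same way on day 2, 63 upward and 111 downward, and 0 went the opposite way. Independent lists of these sizes would share 2.58 and 5.8, and unchanged groups that share the untreated mice gave 0 in 100 simulations. With no probe changed there was little to share, so this 0 cannot show what the shared mice add to the overlap. Over all probes the log2 changes of days 1 and 2 correlated at 0.81, against a mean of 0.478 (highest 0.502) in those simulations. The simulated probes varied independently, so they cannot show how widely this correlation would spread where probes vary together. With the untreated mice split so that each day had its own, a median of 62 (37 to 88 over 20 splits) was shared, of a median of 113 changed on day 1. The correlation was then 0.413 to 0.572. Day 5 shared 2 probes with day 1 and 4 with day 2, each in the same direction, and F13a1 was the 1 probe that went opposite ways on days 2 and 5. The 416 probes that fell on day 2 had a median of -0.82 then and -0.14 on day 5, and 264 of them rose from day 2 to day 5. The 275 that rose had 0.74 and then 0.24, and 82 of them fell. The day 2 mice enter both sides of these last counts, so part of the return is built in. Over the 4 conditions 499 probes changed in the F-test, and those with a single gene name 384 genes.

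The lists below passed on none of days 1, 2 and 5 against untreated in the camera test with a preset correlation. They are given by their medians in that order, with the lowest adjusted p of the 3. Of the lymphocytes, mature B cell genes had 0.19, 0.26 and -0.09 (0.148), T cell genes 0.11, 0.32 and -0.15 (0.688), and genes of NK and cytotoxic cells 0.01, 0.07 and -0.18 (0.236). Of the myeloid cells, dendritic cell genes had 0.15, 0.21 and -0.04 (0.464), neutrophil genes -0.13, -0.43 and 0.11 (0.228), early granule genes 0.06, -0.14 and 0.40 (0.0917), and genes of mast cells, eosinophils and basophils -0.06, -0.05 and -0.06 (0.666). Stem and progenitor cell genes had 0.09, 0.00 and 0.06 (0.61), stroma and endothelium 0.23, 0.18 and 0.15 (0.17), and pancreas genes -0.33, -0.22 and 0.44 (0.127). Of the pathways, DNA repair had -0.04, -0.13 and 0.12 (0.27), p53 targets 0.03, 0.13 and 0.01 (0.298), regulators of apoptosis 0.07, 0.06 and -0.07 (0.688), class I presentation 0.17, 0.30 and -0.10 (0.127) and class II presentation -0.03, 0.00 and -0.11 (0.433). Cytokines had 0.03, 0.04 and -0.07 (0.294), chemokines 0.10, -0.04 and 0.03 (0.531), and cytokine receptors 0.06, 0.08 and 0.00 (0.798). Detoxification genes had 0.04, 0.07 and 0.13 (0.556), immediate early and heat shock genes 0.16, 0.20 and 0.12 (0.228), and ribosomal protein genes -0.05, -0.12 and -0.03 (0.715). Median, mean and test differed in sign on day 1 for T cell genes (test downward, mean 0.07), early granule genes (test downward, mean -0.26) and class II genes (test downward, mean 0.00 after rounding), and on day 5 for cytokine receptors (test downward, mean 0.05). They also did so on day 2 for monocyte genes (test upward, mean 0.00 after rounding), chemokines (test upward, mean 0.11), NK genes (test upward, mean -0.02) and mast cell genes (test upward, mean 0.09).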

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

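The tests of poor arrays, of scaling, cell shares and stroma for the macrophage genes, of marrow-like blood formation, the use of equal spread in every scaling test and all list tests between days were chosen only after the result was seen; the division and platelet scaling tests by quantile normalization, the correlation of mitosis with red cell precursors and the splits of the mice were planned, and the correlation of replication had no outcome set in advance. The tests of poor arrays replaced earlier ones that could not have decided.

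Of the cell division and DNA replication genes 5 and 6 of 14 mitosis genes fell on days 1 and 2 (medians -0.72 and -0.59, adjusted p = 0.0467 on both days with an estimated correlation), and 3 and 7 of 12 replication genes (adjusted p = 0.0599 and adjusted p = 0.179). Scaling between arrays would have to remove the fall. The weakest mitosis median of the 2 days was -0.59 as deposited, -0.42 after quantile normalization and -0.38 with equal spread. Scaling alone thus did not remove the fall of the mitosis list, though it made it smaller. This test did not cover the replication list. Poor arrays would end the fall when their mice are left out. The highest adjusted p of both lists on both days was then 1.99e-07 in the camera test with the preset correlation. That fit kept 3 untreated mice but all 4 day 1 and 5 day 2 mice, so it cannot speak for poor arrays of those days. The technical columns of day 2 mice 1 and 2 differed with SDs of 0.491 and 0.494. Untreated mouse 2, which was left out, had 0.492. With any single mouse left out both lists passed on both days (19 of 19 fits). With group means removed, the mitosis score followed the red cell precursor score over 19 mice (r = 0.643, permutation p = 0.009, 0.012 adjusted over 4 relations; rho = 0.696, p = 0.004; r = 0.61 without the 2 mice farthest from the median), and so did replication (r = 0.751, p = 0.0029, 0.0112 adjusted; rho = 0.604, p = 0.0254; r = 0.694 without the 2). Mice that differ in the size of their response would give such correlations whatever the cause, so these cannot decide. Day 2 mouse 4, for example, was the least low of the day 2 mice in mitosis (-0.15), replication (0.02) and red cell precursors (-0.04). Loss of dividing red cell precursors stays possible for part of the fall, and a fall of division within lymphocytes stays open, as untested.

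Macrophage genes had medians of 0.76 and 0.60 on days 1 and 2, and 1 and 2 of 8 rose (adjusted p = 0.0111 and 0.0383, and adjusted p = 0.254 and adjusted p = 0.299 with an estimated correlation). A lower share of red cell precursors would raise every other cell type alike, but the macrophage score rose over the mean of the T, B and NK scores by 0.425 on day 1 (exact permutation p = 0.00794) and 0.58 on day 2 (0.0159). This compares macrophages with lymphocytes alone. It cannot tell a rise of macrophages from a loss of T, B or NK cells, so a wider change of cell shares stays open. More stroma together with macrophages in the harvest cannot be told apart from a change of macrophages: their score went up over the stroma score by 0.235 on day 1 (exact permutation p = 0.0317) and 0.51 on day 2 (0.0159), but the stroma score itself was higher by 0.27 on day 1 (0.0317, 0.169 adjusted), and with group means removed both scores moved together over 19 mice (r = 0.807, permutation p = 0.001; rho = 0.853; r = 0.791 without the 2 mice farthest from the median). Scaling cannot be told apart from a true rise: quantile normalization and equal spread left medians of 0.55 and 0.58 on day 1 and 0.33 and 0.34 on day 2, with a highest adjusted p of 0.258, so the medians were smaller where the calls ended, and whether this alone ended them was not tested. More macrophages, or more of these transcripts in each, could account for it as well.

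Megakaryocyte and platelet genes had a median of 0.86 on day 5 (adjusted p = 9.72e-09), and 1 of 6 rose, or 4 adjusted over the list alone. That adjusted p rests on the preset correlation of 0.01, since too few members had values on every array for an estimate. In the scores per mouse the exact permutation p was 0.00794, and 0.0847 adjusted. Unequal spread of the arrays would shrink the change, and the median was 0.97 after quantile normalization and 0.88 with equal spread. Day 5 and untreated mice had similar spreads before rescaling (SD 0.382 to 0.524 against 0.41 to 0.53), so this test had little difference to remove. Without the mice of poor arrays the adjusted p was 1.97e-06 with the same preset correlation, while 0 of 6 members rose, so the call of Itga2b was lost there. Blood formation in the spleen that resembles marrow cannot be told apart from a change in the platelet line alone: the red cell precursor score was above all untreated mice in 1 of 5 day 5 mice and the early granule score in 3 of 5. A rise of megakaryocytes or platelets in the spleen is a hypothesis that these data leave open, as the tests that argue against the alternatives were made on the same mice.

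Other splits of the mice argue against chance for the counts of changed probes on days 1 and 2, on day 5 against day 2 and over the 4 conditions. They cannot exclude it, since the smallest share that 100 splits can give is 1 in 100. Nor would they show a batch tied to the day of harvest. For day 5 against untreated they argue against chance by this test alone, and 0 probes passed there under several other settings. Over 100 splits the real split gave the most on day 1 (194, highest other 56), day 2 (691 and 32), day 5 (6 and 2), day 5 against day 2 (441 and 30) and over the 4 conditions (499 and 5), that is 1 split each, the real one. For day 2 against day 1, with 5 changed, 3 of 100 splits gave as many, the real one included, and the highest other gave 14, more than the real count. Why that split gave more was not tested.

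Single values stood far from the rest of their group in 16 of 228 groups tested with Dixon's criterion, where chance gives about 1 in 20. In untreated mouse 4 the macrophage score was -0.67 (others -0.398 to -0.299) and Col14a1 had -0.223 (others 1.036 to 1.475). In untreated mouse 2 Hpcal1 had -2.524 (others -0.523 to -0.44), Hspa1a 0.56 (-0.322 to -0.211), Rhd -2.118 (-0.462 to 0.143) and Nusap1 -1.289 (-0.465 to -0.261). In untreated mouse 3 Kel had -1.189 (others -0.3 to -0.068). On day 1 the monocyte score was -0.024 in mouse 3 (others 0.071 to 0.076), Vav2 was -0.811 in mouse 3 (others -2.078 to -1.99), Col14a1 2.046 (2.542 to 2.605) and App 0.883 (1.095 to 1.139) in mouse 2, and Plpp3 0.776 (2.104 to 2.178) in mouse 1. On day 2 the class I score was 0.463 in mouse 5 (others 0.144 to 0.22), Atp1b1 was -2.053 (others -0.436 to -0.138) and Klk1b5 -1.226 (-3.181 to -2.717) in mouse 1, and Ube2l6 was -1.362 in mouse 4 (others -2.932 to -2.516).

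Lists differed between days in tests of the difference itself. Of the red cell precursor genes 1 of 14 fell from day 1 to day 2 (adjusted p = 0.0126), and the score per mouse differed by -0.11 (exact permutation p = 0.556, 0.809 adjusted). On day 5 against day 2, 6 of 14 mitosis (adjusted p = 1.09e-12), 4 of 12 replication (0.000119), 8 of 14 red cell precursor (2.5e-11) and 2 of 9 heme and iron genes (0.0211) rose. Of the interferon-stimulated, class I and mature B cell genes 3 of 13, 1 of 8 and 2 of 10 fell (0.0137 each). With an estimated correlation mitosis alone stayed past the threshold (adjusted p = 0.038), and the others had adjusted p = 0.365 to 0.738.

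Some probes left out of the tests for missing values were measured in every treated mouse and at most 1 untreated mouse: 25 on day 1, 7 on day 2 and 11 on day 5, against 0 the other way round each time. The number of probes with values differs between mice and was not allowed for. Untreated mice 1 and 5 had 7817 and 7573, the other untreated mice 8775 to 9919 and the day 1 mice 8698 to 10087. The probes left out include Cfb (log2 ratio to marrow 0.15 ± 0.40 SD, n = 4) and Cd14 (0.04 ± 0.17) on day 1 and Saa3 (-0.07 ± 0.17, n = 5) on day 2.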

How the results depend on the processing

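Scaling to equal spread and the fit without the 3 mice of lowest technical correlation were chosen only after the result was seen; the other settings were chosen before the data were examined. In every case the cause was not tested, except that stricter thresholds lower a count by construction. The values are to be set beside 194, 691, 6, 5 and 441 changed probes (days 1, 2 and 5, day 2 against 1, day 5 against 2), 499 probes changed over the 4 conditions (F-test), 6, 7 and 5 lists, and, as the measure of genes changed on more than 1 day, 174 probes shared by days 1 and 2. Quantile normalization gave 338 (day 2), 0 (day 2 against 1), 83 (day 5 against 2), 285 (F-test) and 4 lists on day 2, and on day 5 3 risers and 3 fallers against 4 and 2. Equal spread gave 116 (day 1), 345 (day 2), 0 (day 2 against 1), 142 (day 5 against 2), 263 (F-test), 3 lists on day 1, 4 on day 2 and 92 shared probes, and F13a1 on day 2 went from -0.85 to 0.126 (adjusted p = 0.896). The random effect gave 452 (day 1), 24 (day 5), 27 (day 2 against 1), 730 (day 5 against 2) and 916 (F-test), and array weights 403 (day 1) and 25 (day 2 against 1). On day 5, 0 probes passed with the first or the second technical column alone, with a variance trend, with averaged probes, with a block on mouse number or at adjusted p below 0.01, 1 with only the groups compared, 1 without the 3 mice and 11 without a filter. Day 2 against 1 gave 8 without a filter, 3 with the trend, 3 with the block, 2 with averaged probes and 1 with only the groups compared, and the block left 4 lists on day 2. Adjusted p below 0.01 gave 76, 316, 3 (day 2 against 1), 192, 261 (F-test) and 72 shared; a 2-fold change 83, 194, 148 (day 5 against 2) and 188 (F-test). Day 2 gave 449 with only the groups compared; without the 3 mice days 1 and 2 gave 113 and 409. An estimated correlation left 1, 1 and 0 lists, and fry 0 on day 5. On days 1 and 2 the mitosis, replication, red cell precursor, macrophage and helper T lists passed with fry (highest adjusted p = 0.0209). The heme and iron list did so on day 2 (0.00615), and the interferon list missed on day 1 (0.0659). With fry cytokines also passed on days 1 and 2 (0.00755 and 0.00615). On day 2 fry further passed the regulatory T list (0.00615) and the germinal centre and plasma cell list (0.00615), both downward. It also passed the detoxification list (0.0173), upward. The estimated correlation and fry both used only members with values on every array (9 of 14 for mitosis, 4 of 8 for macrophages), so 2 choices changed together, and neither could test the megakaryocyte and monocyte lists. Over single mice left out the counts were 99 to 219, 503 to 683, 0 to 5, 3 to 9, 296 to 452 and 388 to 484, and 4 to 8, 3 to 7 and 3 to 7 lists; the lowest list counts were 3 on day 2 without day 2 mouse 1 (4 without untreated mouse 4, day 2 mouse 2 or day 2 mouse 5) and 3 on day 5 without untreated mouse 5. The direction of the deposited ratio, as the gap between lymphocyte and granule lists, was 1.279, and 1.132 with T cell against early granule genes. Of 418 named results, 99 past the threshold, 163 of 14470 alternatives changed sign with neither value past it. List tests between days were also run with an estimated correlation and with fry, and under no other setting; with fry red cell precursors from day 1 to 2 (adjusted p = 0.325) and class I genes from day 2 to 5 (0.236) missed the threshold, and cytokines (0.00047), macrophages (0.021) and early granule genes (0.0431) passed it from day 2 to 5. Missing values, 5829 to 10407 present per array, limit what can be tested; signal over background is not given in the sources used here.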

Other observations

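The test of the 8 probes below against red cell precursors was planned after the genes were named and before its result was seen, and that against mitosis had no outcome set in advance.

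Vav2, Klk1b5, Syt9, Tuba3a, Ube2l6, Mgst3, Ctse and Btnl10 fell with the red cell genes, and none of them is in the red cell precursor list. With group means removed, the mean of these 8 probes followed the red cell precursor score over 19 mice (r = 0.753, permutation p = 0.0056, 0.0112 adjusted over 4 relations; rho = 0.649, p = 0.014), and r was 0.626 without the 2 mice farthest from the median. Against the mitosis score r was 0.309 (p = 0.225, 0.225 adjusted; rho = 0.3, p = 0.253; 0.194 without the 2). These probes may report red cell precursors in the spleen, a hypothesis from the same mice in which the fall was found. Mice that differ in the size of their response could give such a correlation too.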
